A study of Rattus norvegicus with 8 samples.

How the data were processed

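RNA of the C6 rat glioma line was profiled on 8 Affymetrix rat arrays, with the description migration in the labels. Groups were taken from the sample titles: C6 slow, C6 fast, C6SPGFP slow and C6SPGFP fast, 2 arrays each. The meaning of C6SPGFP, how fast and slow cells were separated and whether replicates were separate cultures are not given in the sources used here.

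The deposited values are linear probe set signals of intensity, from 0 to 14287.9, never negative, for 8799 probe sets, 59 of them controls. The software that made them is not given in the sources used here. From the values, each array appears to have been scaled alone to a global target: the 2% trimmed mean was between 100.1 and 105.8 on 7 arrays and 500.5 on C6SPGFP fast replicate 1. Detection calls are not used here, so no rule on signal above background was applied, and signals of a few units are not shown to be above background.

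The choices below were made before the data were examined, unless stated otherwise. The deposited scaling was to be kept if the trimmed means lay within 10% of each other, and quantile normalization of the signals between arrays was to be used if not; the latter applied. Values were taken as log2 of the normalised signal plus a pseudocount of 8, the 25th percentile of all values. Probe sets with a mean normalised signal of at least 8 over the 8 arrays were tested (6684), and 2056 below it were left out. Log2 changes of genes with low signals are drawn towards 0 by the pseudocount, and the folds given are those of signal plus pseudocount. Group means and SDs are of the normalised signal without pseudocount.

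A linear model with 4 group means was fitted to the 8 arrays with limma (lmFit and eBayes with a trend on mean level), two-sided, with Benjamini-Hochberg adjustment at 5% over all probe sets tested within a comparison. The comparisons were fast minus slow in C6 and in C6SPGFP, their mean, their difference (C6SPGFP minus C6), and C6SPGFP minus C6 in slow cells, in fast cells and on the mean. The fit left 4 residual degrees of freedom and 4.49 prior ones, and the median SE was 0.241 in a single set, 0.17 on a mean and 0.341 on the difference (log2). An unadjusted p under 0.05 was reached by 1296 probe sets in C6, 648 in C6SPGFP, 1120 on their mean, 1030 on the difference, and 1401, 1932 and 2123 between the sets in slow cells, fast cells and on the mean. The correlation of the fast minus slow changes between the sets was computed across probe sets, which are not independent replicates; the 2 changes share no array. Overlap of calls was tested with Fisher's exact test in each direction, although both changes of a probe set were tested with the same estimate of its spread.

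Gene names came from the platform's probe table: 7018 probe sets carried a single symbol, 308 several and 1473 none, and the last 2 kinds were tested but not named. Of the first, 6994 were brought to current symbols through their Entrez identifier in a rat annotation table of assembly GRCr8, used for names only, and 24 kept the symbol of the probe table. A probe set's position in the genome is not used here.

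There were 23 gene lists, each with at least 3 measured members and a single probe set per gene, the one with the highest mean signal, so that a gene's value in a list can differ from its value as a named gene. They covered regulators of G-protein signalling, extracellular matrix, proteases and inhibitors, adhesion, actin and contractility, astroglial, oligodendroglial and Schwann, neuronal, microglial and haematopoietic, and endothelial and mural genes, proliferation, growth inhibitors and quiescence, growth factors and receptors, chemokines and cytokines, sterol and fatty acid synthesis, glycolysis, immediate early genes, heat shock and unfolded protein stress, oxidative stress and detoxification, interferon and antigen presentation, oxidative phosphorylation, ion channels and transporters of migration, and cytosolic ribosomal proteins. Some genes stand in more than 1 list, such as S100b among the astroglial and the oligodendroglial genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Members were counted at 5% over all probe sets and adjusted over the list alone. The list tests on the difference and between the sets were added after the data had been seen.

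The genes named were, per comparison, the 12 largest increases and the 12 largest decreases among called probe sets with a single symbol and no overlap between the arrays of the groups compared within each set, 1 probe set per gene, that with the largest change. Added to these were the 6 genes with the smallest p in each direction of the difference, up to 2 called members per direction of a list, and always Rgs3 and Rgs4, which the study group is known to have followed up, and Vim, Gfap and S100b for the glial identity of C6 cells. Gfap and Rgs3 had no probe set named for them. Some further list members, and the genes called in both sets, were named after their values were seen.

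RNA quality was read from the 3'/5' ratios of the control probe sets for Gapdh, beta-actin and hexokinase and from the 5S and hybridisation controls of each array. The mean log2 signal of the ribosomal protein genes, those of the ribosomal list, was tested beside these. The tests were two-sided exact permutation tests of 4 against 4 arrays (70 splits), with adjustment over 12 tests.

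The procedure was tested on simulated data with the spread of these arrays. A change of log2 1 was recovered for 40.1% of probe sets in C6, 40.5% in C6SPGFP, 67.2% on their mean, 11.6% on the difference and 69.2% between the sets, and a change of log2 2 for 85.6%, 85%, 94.6%, 56.1% and 95.1%. False calls were 3.3% to 5.3% of all calls, and 20 simulations without effect gave 0 calls and 0 lists on the mean of both sets. The simulated probe sets varied independently of each other. The 0 lists therefore do not cover lists whose members move together, such as the sterol list (estimated correlation 0.71).

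Alternatives were the deposited scaling, each array scaled to the same median, pseudocounts of 2 and 38, no filter and a filter at 38, moderation without the trend, each array left out in turn, the replicate number as a block, fits of only the groups compared and, for lists, an estimated correlation and the mean of all probe sets of a gene. Scaling each array to a trimmed mean of 100 was added after the scale of the arrays had been seen. Where an array is left out, the lone array of its group is assumed to vary like the other groups.

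Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.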

Results

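RNA of C6 cells, a rat glioma line with glial features, was measured on 8 oligonucleotide arrays, and the labels give migration as the subject. The arrays fell into 4 groups of 2: slow and fast cells of the C6 line, and slow and fast cells of a set labelled C6SPGFP, a name that the labels do not explain. Each array held 8799 probe sets, of which 59 were controls. The 2% trimmed mean of the deposited signal lay between 100.1 and 105.8 on 7 arrays and was 500.5 on C6SPGFP fast replicate 1, so the arrays were quantile normalised before they were compared, to a trimmed mean of 150.9. Of the probe sets, 6684 with a mean normalised signal of at least 8 were tested, and 5462 of these carried a single gene symbol, for 3878 genes. The number of arrays, 2 per group, limits the precision of every value. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which is possibly technical.

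The C6 fast arrays stood apart from the rest. Across probe sets, which are not independent replicates, Pearson's r between replicates of a group lay between 0.9693 and 0.9778, and r between C6SPGFP slow and fast arrays lay between 0.960 and 0.971. Between C6 slow and C6 fast arrays r was 0.923 to 0.939, lower than between C6 slow and C6SPGFP fast arrays, at 0.946 to 0.955. Vim, the intermediate filament vimentin that C6 cells make in large amounts, had a signal of 2881 ± 284 (SD, n = 2) in C6 slow, 2658 ± 91.3 in C6 fast, 3179 ± 109 in C6SPGFP slow and 3716 ± 162 in C6SPGFP fast cells. The 3'/5' ratios of the Gapdh and beta-actin controls, a measure of RNA integrity, did not separate fast from slow arrays (two-sided exact permutation p = 0.771 and 1). Nor did the hexokinase ratio, at 1.72 ± 0.185 on fast and 1.83 ± 0.311 on slow arrays (SD, n = 4; two-sided exact permutation p = 0.543). These tests took the fast arrays of both sets together, so they do not test the C6 fast arrays alone. The Gapdh ratio was 1.052 and 1.002 on the C6 fast and 1.029 and 1.008 on the C6 slow arrays. The beta-actin ratio was 1.033 and 1.032 against 1.006 and 1.009. A hybridisation control, relative to the trimmed mean, was 12.14 and 13.95 against 17.86 and 18.21. Rgs3 and Rgs4, regulators of G-protein signalling that the study group is known to have followed up, could not be tested. No probe set was named for Rgs3, and the single probe set of Rgs4 lay below the filter, with signals of 2.72, 2.50, 3.11 and 2.20 in C6 slow, C6 fast, C6SPGFP slow and C6SPGFP fast cells.

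The comparison of fast with slow C6 cells asks which transcripts go with faster migration in this line. Tubb2b, a beta-tubulin of the nervous system, fell from 1686 ± 79.7 to 33.0 ± 1.43 (SD, n = 2), 41.3-fold. Sox10, the transcription factor of the oligodendrocyte and Schwann cell lineages, fell from 304 ± 89.8 to 1.56 ± 0.937. The calcium-binding glial protein S100b fell 5.67-fold, from 408 ± 18.4 to 65.9 ± 12.8 (log2 change -2.50 ± 0.16, SE). Its other probe set gave a log2 change of -0.187. Ccl2, a chemokine that attracts monocytes, fell from 1820 ± 95.9 to 52.1 ± 9.10. Atp1b1, the beta subunit of the sodium-potassium pump, rose from 3.27 ± 1.55 to 399.6 ± 3.9. The laminin chain Lama3, part of basement membranes, rose from 20.5 ± 0.455 to 426 ± 130.

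Pla2g4a, the phospholipase that frees arachidonic acid, rose by 4.81 ± 0.31 (SE) on the log2 scale in fast C6 cells. Ptgs2, the cyclooxygenase that turns arachidonic acid into prostaglandin, rose by 3.69 ± 0.24. Srpx, a sushi-repeat protein, rose by 4.25 ± 0.21 and galectin 3 (Lgals3) by 3.39 ± 0.33. The other large increases were those of Pou3f3, Olfm1, Rtn1, Lsamp, the fructose transporter Slc2a5 and the cyclic nucleotide phosphodiesterase Pde2a, with log2 changes from 3.04 to 3.64. The other Olfm1 probe set gave 0.402. Large decreases were also found for Aatk (-4.63 ± 0.15), the TGF-beta signalling inhibitor Pmepa1 (-4.48 ± 0.12), the homeobox gene Rhox5 (-4.41 ± 0.16) and the cytochrome Cyp1b1 (-3.93 ± 0.39). The neuropeptide gene Calcb (-3.92 ± 0.17), the tetraspanin Cd81 (-3.90 ± 0.23), Bin1 (-3.63 ± 0.35), reelin (Reln, -3.50 ± 0.34) and tissue factor (F3, -3.45 ± 0.24) followed. The other Rhox5 probe set gave 0.308, and other probe sets gave smaller changes for Atp1b1 (2.28), Ptgs2 (1.86), Slc2a5 (1.79), Rtn1 (1.69), Cyp1b1 (-1.33) and Bin1 (-1.29). The adjusted p-values of these 24 genes ran from 1.36e-07 for Tubb2b to 0.000474 for Cyp1b1. Each was separated on all 4 arrays, which the rule for naming genes required. Vim did not pass the test, with a log2 change of -0.11 ± 0.10 (adjusted p = 0.611).

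In all, 445 of 6684 probe sets passed in C6, 180 higher and 265 lower in fast cells, of which 132 and 215 changed more than 2-fold. They covered 126 genes that rose and 184 that fell. The count was 292 without C6 slow replicate 1 and 279 without C6 fast replicate 2. It was 230 when only the C6 arrays were fitted and 24 under the deposited scaling.

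Lists of glial genes moved down in fast C6 cells at the preset correlation. Of 18 measured oligodendroglial and Schwann genes, 4 fell and none rose, both over all probe sets and adjusted over the list alone. They included Sox10 and Cnp, a myelin enzyme (-2.23 ± 0.18). The list as a whole moved down (camera adjusted p = 0.0123; adjusted p = 0.459 with an estimated correlation). Of 19 astroglial genes, 5 fell, or 6 adjusted over the list alone, among them Ndrg2 (log2 change -3.08) and Fabp5 (-2.79). The list moved down with an adjusted p of 0.0181 (adjusted p = 0.47 with an estimated correlation). Negative changes were found for 13 of 18 oligodendroglial and 11 of 19 astroglial genes, and positive ones for 5 and 8. The medians were -0.22 and -0.11 against means of -0.74 and -0.63, so large falls of some members drew the means down. Both list calls depended on single arrays. The oligodendroglial call ended without C6 slow replicate 2 (adjusted p = 0.0587). The astroglial call ended without C6 slow replicate 2 (0.149) or C6 fast replicate 1 (0.0707). Of the microglial and haematopoietic markers, 1 of 16 rose in fast C6 cells, Cd37, by 1.41 on the log2 scale, and none of 11 endothelial and mural markers passed.

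Several lists held strong single members without passing as a whole in C6. Of 65 growth factors and receptors 4 rose and 8 fell, the same numbers adjusted over the list alone (list adjusted p = 0.115). Gfra1, a receptor for GDNF, was at -2.96, Ptprz1 at -3.27, Igf1 at 2.04 and Efna1 at 1.53. Of 40 neuronal genes 1 rose and 3 fell, also adjusted over the list alone (list adjusted p = 0.162). Of 34 adhesion genes 3 fell, or 4 adjusted over the list alone with 2 higher (list adjusted p = 0.342). The 3 were the tetraspanins Cd81 and Cd9 (-2.61) and the integrin chain Itga1 (-3.15). Of 49 actin and contractility genes 5 fell, or 7 adjusted over the list alone, led by ezrin (Ezr, -2.40) and Capg (-1.87), with a list adjusted p of 0.126. Of 4 measured regulators of G-protein signalling 2 fell, also adjusted over the list alone, Rgs12 (-1.21) and Rgs14 (-1.06), with a list adjusted p of 0.32. With the filter at the 50th percentile 8 lists passed in C6 instead of 4. The added ones, each lower in fast cells, were extracellular matrix (adjusted p = 0.00896), actin and contractility (0.0436), growth inhibitors (0.0436) and immediate early genes (0.0476).

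Sterol and fatty acid synthesis genes moved up as a list in C6 (18 of 21 with a positive change, adjusted p = 0.0181; adjusted p = 0.633 with an estimated correlation). No member passed the test over all probe sets or adjusted over the list alone. The call ended without C6 slow replicate 1 (adjusted p = 0.986) or C6 fast replicate 2 (0.159). Proliferation genes also moved up as a list (25 of 33 positive, adjusted p = 0.0497; adjusted p = 0.47 with an estimated correlation). The single member that passed, the cyclin Ccne1, which drives entry into DNA synthesis, was lower in fast cells (-0.87), and no member passed adjusted over the list alone. That call held in 1 of 8 runs that each left out an array, with adjusted p-values from 0.0679 to 0.273 in the other 7. It also ended with the replicate number as a block (adjusted p = 0.0645) and under the deposited scaling (0.195). In C6 the median (0.036) and the mean (-0.037) of the microglial list differed in sign, and its test pointed down.

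**Figure D1:**
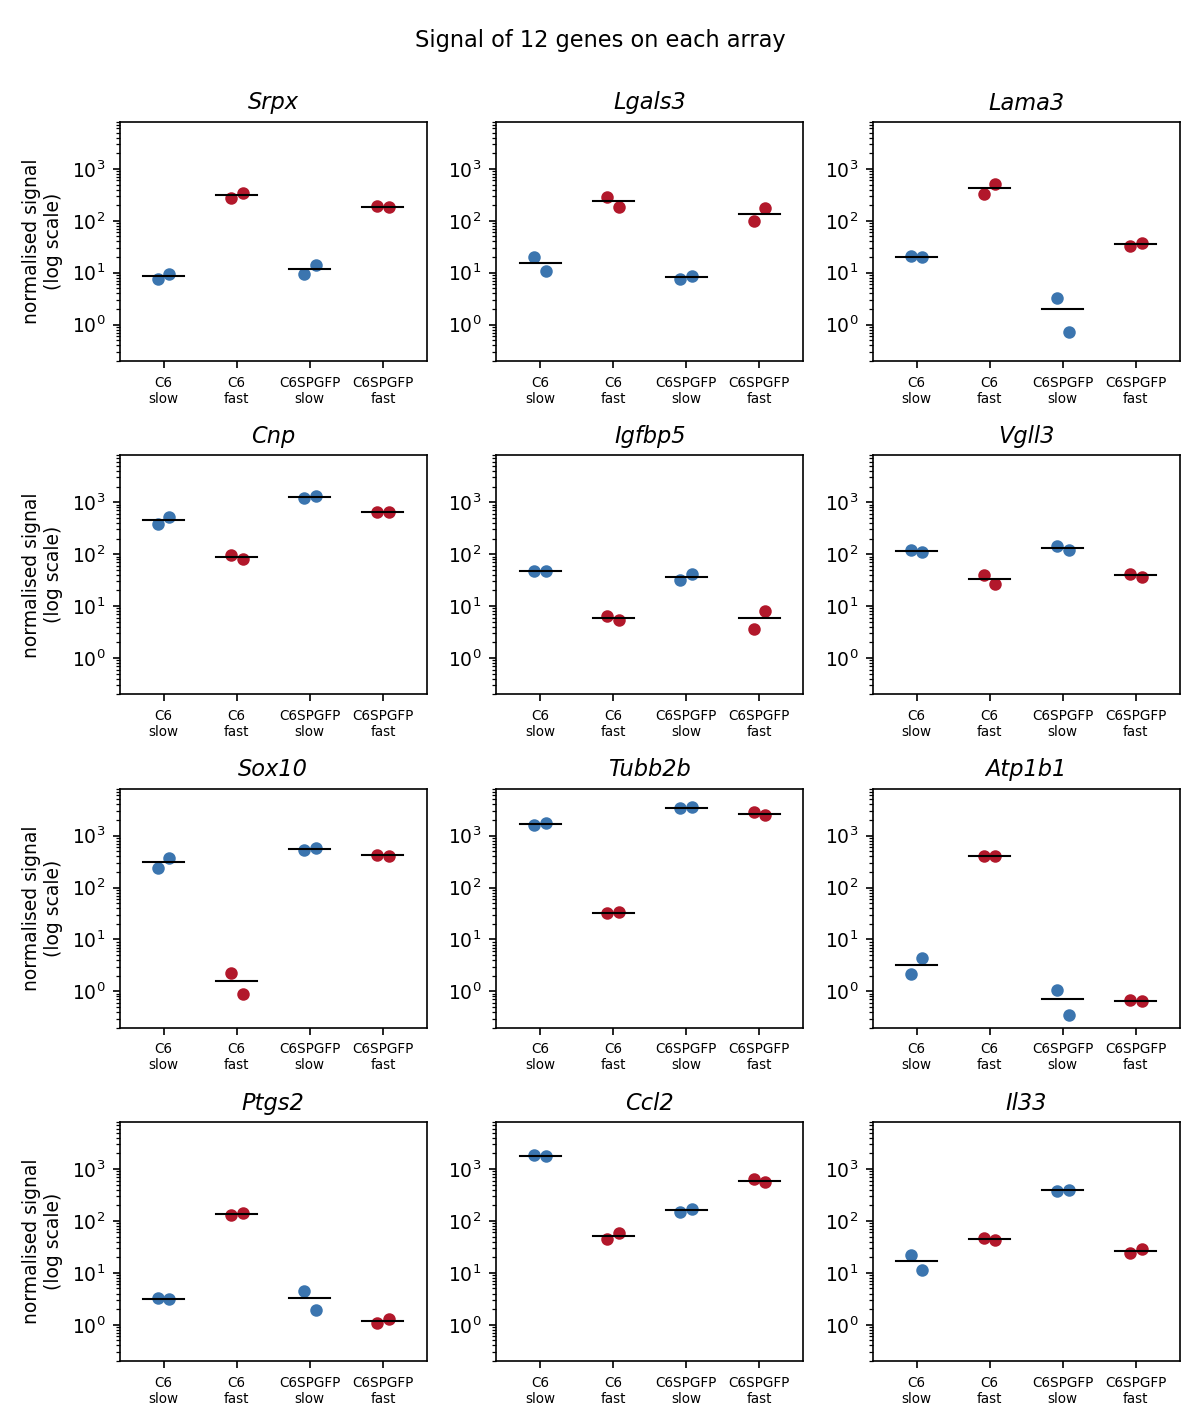
Normalised signal (vertical axis, log scale) of 12 genes on each of the 8 arrays, by group; points are arrays, blue slow and red fast, and bars are group means. Srpx, Lgals3 and Lama3 were higher in the fast cells of both sets, whereas Sox10 and Atp1b1 differed between fast and slow cells by more than 4 log2 units in C6 and by -0.38 and -0.01 in C6SPGFP.

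In the C6SPGFP set the same question was asked. Sncg, gamma-synuclein, a protein of neurons, rose from 1.79 ± 0.371 in slow to 190.0 ± 64.7 in fast cells (SD, n = 2). Spn, a sialoglycoprotein of the cell surface, rose from 2.86 ± 1.14 to 134 ± 3.79, and the water channel Aqp1 from 7.48 ± 0.115 to 186 ± 4.0. Podoplanin (Pdpn), a membrane mucin, rose from 4.64 ± 0.239 to 124 ± 18.2, and follistatin (Fst), which binds activins, rose 5.14-fold. Il33, a cytokine kept in the nucleus, fell from 387 ± 16.5 to 26.3 ± 3.07. Matrix Gla protein (Mgp), an inhibitor of calcification, fell from 2578 ± 146 to 350 ± 45.0, and the glial potassium channel Kcnj10 from 92.9 ± 43.8 to 6.99 ± 1.5.

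The remaining large increases in C6SPGFP fast cells were Gnrhr (log2 change 3.44 ± 0.24, SE), the urea cycle enzyme Ass1 (3.38 ± 0.24), Srpx (3.28 ± 0.21) and Lgals3 (3.12 ± 0.33). They also included the synaptic vesicle protein Sv2b (2.77 ± 0.25), Jph2 (2.66 ± 0.35) and the forkhead gene Foxs1 (2.50 ± 0.27). The remaining decreases were smaller, from -1.44 for the phosphatase subunit Ppp2r2b to -1.80 for gephyrin (Gphn). They included Prkcb, Errfi1, the insulin-like growth factor binding proteins Igfbp3 and Igfbp5, Basp1, carboxypeptidase E (Cpe) and Vgll3. Other probe sets gave smaller changes, down to -0.163 for Prkcb, -0.449 for Errfi1, -0.781 for Kcnj10, -0.942 for Igfbp5, -0.59 for Ppp2r2b and 1.17 for Gnrhr. Adjusted p-values of these 24 genes ran from 0.000255 for Spn to 0.0319 for Errfi1. Each was separated on all 4 arrays, which the rule for naming genes required. Vim (0.22 ± 0.10, adjusted p = 0.506) and S100b (0.04 ± 0.16, adjusted p = 0.965) did not pass.

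In all, 93 probe sets passed in C6SPGFP, 71 higher and 22 lower in fast cells (53 and 19 genes), of which 64 and 18 changed more than 2-fold. The count was 25 without C6SPGFP slow replicate 2, 34 without fast replicate 1 and 21 without fast replicate 2. Of 24 named genes, 13 lost the call in at least 1 run without an array, namely Aqp1, Cpe, Errfi1, Foxs1, Gphn, Igfbp3, Igfbp5, Jph2, Kcnj10, Mgp, Ppp2r2b, Prkcb and Vgll3. Their adjusted p-values then lay between 0.0524 and 0.189 without fast replicate 1 and between 0.0534 and 0.203 without fast replicate 2. They lay between 0.053 and 0.195 without slow replicate 1 and between 0.0613 and 0.215 without slow replicate 2. The calls for Errfi1, Igfbp3 and Ppp2r2b also ended under another pseudocount, and in part without the filter or the trend in the moderation (adjusted p from 0.0508 to 0.0653). Under the deposited scaling C6SPGFP fast replicate 1 stays at its own scale, and the median change of all probe sets was 1 instead of -0.02. There 20 probe sets passed, 100% of them higher, against 76.3%.

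Of the lists, 5 passed in C6SPGFP. Oxidative stress and detoxification genes rose as a list (23 of 31 positive, adjusted p = 0.000152; adjusted p = 0.199 with an estimated correlation). In it 1 member was called, the quinone reductase Nqo1 (2.0), or 4 adjusted over the list alone. Chemokines, cytokines and receptors rose as a list (21 of 29 positive, adjusted p = 0.0013; adjusted p = 0.199 with an estimated correlation). In it 3 were called, or 4 adjusted over the list alone, among them the cyclooxygenase Ptgs1 (2.10), which makes prostaglandin and is no cytokine, and Ccl2 (1.60). Proliferation genes rose as a list (30 of 33 positive, median log2 change 0.23, adjusted p = 0.000231; adjusted p = 0.199 with an estimated correlation). No member passed the test, also adjusted over the list alone. Interferon and antigen presentation genes rose as a list (15 of 23 positive, adjusted p = 0.00432; adjusted p = 0.25 with an estimated correlation). In it 1 was called, the immunoproteasome subunit Psmb9 (1.09), or 6 adjusted over the list alone. The call ended without C6SPGFP slow replicate 1 (adjusted p = 0.282).

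Oligodendroglial and Schwann genes fell as a list in C6SPGFP fast cells too (13 of 18 negative, adjusted p = 0.0142; adjusted p = 0.199 with an estimated correlation). The 2 members called, also adjusted over the list alone, were Cnp (-0.93) and the adhesion molecule Ncam1 (-0.81), while Sox10 was at -0.38 ± 0.22 (adjusted p = 0.635). The call ended without C6SPGFP slow replicate 1 (adjusted p = 0.146) or fast replicate 1 (0.0712), and under the deposited scaling (0.0752). No microglial or haematopoietic marker of 16 and no endothelial or mural marker of 11 passed, over all probe sets or adjusted over the list alone. In C6SPGFP the adhesion list had a median of -0.03 and a mean of 0.014 with a test pointing up. The ion channel list had a median of 0.0066 and a mean of 0.081 with a test pointing down.

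The fast minus slow changes of the 2 sets had little in common. Across the 6684 probe sets, which are not independent replicates, Pearson's r between the changes in C6 and in C6SPGFP was 0.051 and Spearman's rho 0.0467. Among the 503 probe sets called in either set r was 0.117 and 55.7% had the same sign. In the fast cells of both sets 14 probe sets were higher, against 1.91 expected if the calls were independent (Fisher's exact p = 4.01e-09). Another 6 were lower in both, against 0.872 expected (Fisher's exact p = 0.00016). Calls in opposite directions exceeded the expected number too. In C6 5 were higher and in C6SPGFP lower, against 0.592 expected (Fisher's exact p = 0.000243), and 10 were lower in C6 and higher in C6SPGFP, against 2.81 (Fisher's exact p = 0.00044). The excess of shared calls was thus not limited to changes in the same direction. Both changes of a probe set were tested with the same estimate of its spread, which can by itself raise the number called in both. Some genes, such as Maf, Fst and Ccl2, were also counted on more than 1 probe set. These p-values are therefore no test of a shared effect. The genes that rose in both were Srpx, Lama3, Lgals3, Spn, the glutathione transferase Gstk1, the transcription factor Maf, Medag, ankyrin 3 (Ank3), Sfxn1, proenkephalin (Penk), the small heat shock protein Hspb6 and the mitochondrial isocitrate dehydrogenase Idh2. Those that fell in both were Cnp, Igfbp5, the lysosomal lipase Lipa and Vgll3. Some of these calls were weak in C6SPGFP, with limma adjusted p-values of 0.0468 for Idh2, 0.0453 for Cnp and 0.03 for Gstk1 and Ank3. For Spn and Srpx they were 0.000255 and 0.000316. Igfbp5 and Vgll3 were among the genes given above whose C6SPGFP call ended without an array.

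**Figure D2:**
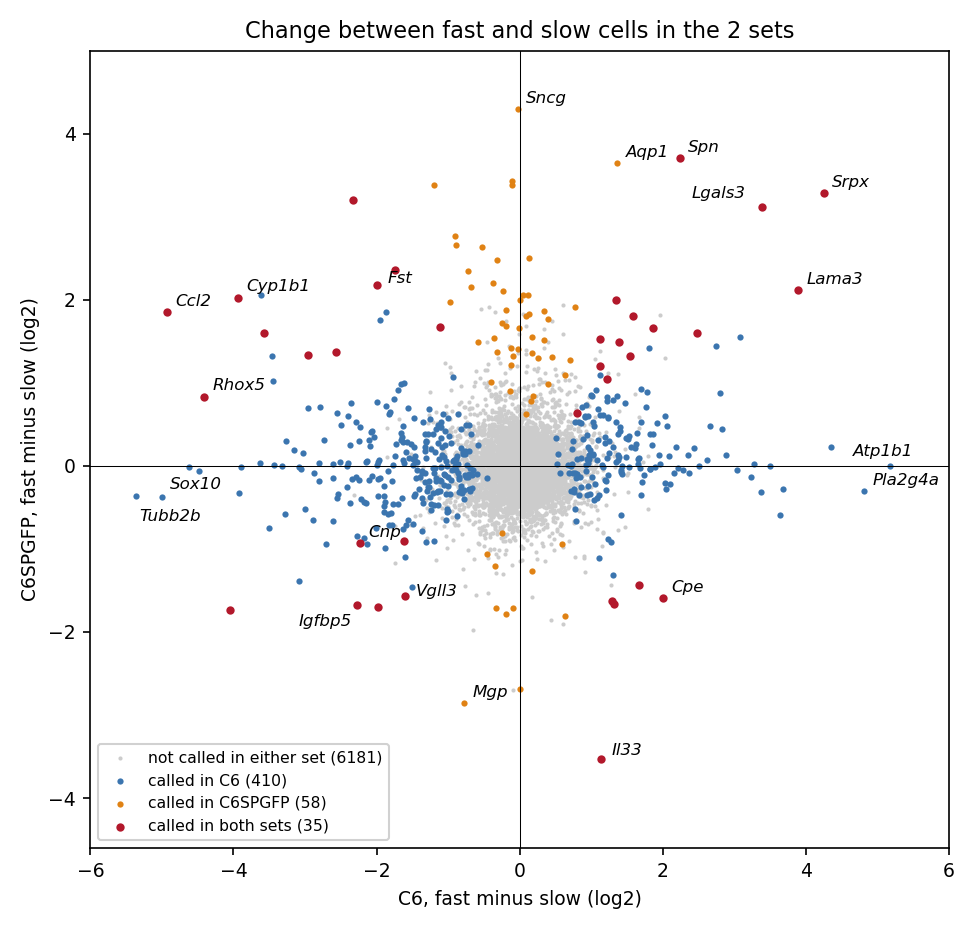
Log2 change between fast and slow cells in C6 (horizontal axis) and in C6SPGFP (vertical axis) for each of 6684 probe sets, coloured by the set in which the change passed the test. The changes were nearly uncorrelated (Pearson's r = 0.051 across probe sets), with 35 probe sets called in both sets, 15 of them in opposite directions.

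The difference between the sets was tested directly, as the C6SPGFP change minus the C6 change. Ccl2 fell in C6 and rose in C6SPGFP, from 160.0 ± 14.7 to 599 ± 49.0 (SD, n = 2), a difference of 6.79 ± 0.24 (SE; adjusted p = 3.64e-06). Follistatin fell in C6 (-1.75) and rose in C6SPGFP (2.36), and Rhox5 fell in C6 and rose in C6SPGFP (0.83, adjusted p = 0.0414). Il33 rose in C6 (1.14) and fell in C6SPGFP (-3.53), and Basp1 rose in C6 (1.32) and fell in C6SPGFP (-1.67). Tubb2b, Pmepa1 and Aatk fell in C6, with differences of 5.0 ± 0.17, 4.42 ± 0.17 and 4.61 ± 0.22. Atp1b1, Pla2g4a, Pou3f3 and Ptgs2 rose in C6, with differences of -5.19 ± 0.32, -5.12 ± 0.44, -4.23 ± 0.34 and -3.97 ± 0.34. These 12 genes, those with the 6 smallest p-values in each direction, had adjusted p-values up to 0.000433. The other Rhox5 probe set gave a difference of -0.504, and other probe sets of Atp1b1 and Ptgs2 gave smaller ones, down to -2.34 and -1.6. In all, 15 probe sets were called in opposite directions in the 2 sets, among them those of Cyp1b1, Bmp7, Mmp16, Cpe, Ppp2r2b and Asgr1.

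The test of the difference called 255 probe sets, 181 with the higher change in C6SPGFP and 74 with the higher change in C6 (132 and 54 genes), 177 and 71 of them by more than 2-fold. The count was 139 without C6SPGFP slow replicate 1, 126 without slow replicate 2, 128 without fast replicate 1 and 123 without fast replicate 2. It was 25 under the deposited scaling, 96% of them with the higher change in C6SPGFP against 71%, where the median of all probe sets was 1.1 instead of -0.038.

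Astroglial genes differed as a list between the sets (14 of 19 with the higher change in C6SPGFP, adjusted p = 0.0059; adjusted p = 0.362 with an estimated correlation). In it 4 were called, S100b, Fabp5 (3.49), Ndrg2 (3.07) and nestin (Nes, 1.62), or 6 higher and 1 lower adjusted over the list alone. The chemokine list differed too (adjusted p = 0.0264; adjusted p = 0.362 with an estimated correlation). It had 4 called, or 6 higher and 2 lower adjusted over the list alone, with Ccl2 and the chemokine receptor Ackr3 (2.57) among them. So did the oxidative stress list (adjusted p = 0.0264; adjusted p = 0.362 with an estimated correlation). It had 3 higher and 1 lower, or 5 and 1 adjusted over the list alone, with Cyp1b1 (4.78 on the probe set used for lists) and Gstm2 (-1.57). The sterol list was lower in C6SPGFP by this measure (18 of 21 negative, adjusted p = 0.0274; adjusted p = 0.603 with an estimated correlation), with Acat2 (-1.16) called, also adjusted over the list alone. The chemokine call ended without C6 slow replicate 1 (adjusted p = 0.0855) or C6 fast replicate 1 (0.0514), and the oxidative stress call without C6 slow replicate 1 (0.0855) or C6 fast replicate 2 (0.0981). The sterol call ended without C6 slow replicate 1 (0.555), C6 fast replicate 2 (0.161) or C6SPGFP fast replicate 1 (0.0608). The oxidative stress call also ended with each array scaled to the same median (0.0692) or to a trimmed mean of 100 (0.0661) and with the filter at the 50th percentile (0.06). That filter also ended the chemokine call (0.0645) and added the neuronal list (0.00646 against 0.114), and the deposited scaling ended the sterol call (0.0646). The oligodendroglial list (adjusted p = 0.21), the proliferation list (0.706) and the interferon list (0.125) were not shown to differ. For adhesion the median was -0.025 and the mean 0.24, and for proliferation -0.037 and 0.044, with tests pointing up.

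The mean of the 2 fast minus slow changes asks which transcripts go with speed on average over the sets. A change in a single set can be enough to pass it. Srpx led the increases at 3.77 ± 0.15 (SE) on the log2 scale, 13.6-fold. Its signal went from 8.60 ± 1.49 to 309 ± 44.0 in C6 and from 12 ± 3.3 to 186 ± 5.47 in C6SPGFP (SD, n = 2). Lgals3, a lectin that binds cell surface glycans, rose by 3.26 ± 0.23, Lama3 by 3.01 ± 0.18 and Spn by 2.98 ± 0.14. Aqp1 (2.51), plakoglobin (Jup, a junction protein, 2.10), Gstk1 (2.04) and the Wnt antagonist Sfrp4 (1.89) came next. Cdc42ep3, an effector of the Cdc42 GTPase (1.84), Maf (1.76), Medag (1.69) and Sfxn1 (1.67) followed. Of these 12, Aqp1 did not pass in C6 (1.37, adjusted p = 0.109), Jup (1.45, 0.225) and Cdc42ep3 (0.88, 0.139) did not pass in C6SPGFP, and Sfrp4 passed in neither set (0.0921 and 0.286). The test of the difference passed for Cdc42ep3 (adjusted p = 0.0114), Lama3 (0.0355) and Spn (0.0263), so the size of their change was not shared. Igfbp5 (-1.84 ± 0.18), Vgll3 (-1.58 ± 0.16) and Cnp (-1.58 ± 0.12) were the large decreases that passed in each set. Cnp also passed the test of the difference (adjusted p = 0.0243), with the larger fall in C6. Other probe sets gave smaller mean changes for Gstk1 (0.5), Maf (0.912), Prickle2 (-0.907), Pkia (-0.792) and S100b (-0.123).

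The other large decreases on the mean were carried mainly by C6. Tubb2b (-2.87 ± 0.08), Sox10 (-2.69 ± 0.16), Reln (-2.13 ± 0.24), Calcb (-2.13 ± 0.12), Prickle2 (-1.93 ± 0.13), the motor protein Kifc3 (-1.76 ± 0.21) and the zinc finger gene Plagl1 (-1.63 ± 0.16) each also passed the test of the difference. So did the oestrogen receptor Gper1 (-2.24 ± 0.19; adjusted p of the difference 0.0491), whereas Pkia (-1.83 ± 0.24) did not (adjusted p of the difference 0.105). S100b fell on the mean (-1.23 ± 0.11, adjusted p = 0.000607) with a change of 0.04 in C6SPGFP. Vim did not pass (0.06 ± 0.07, adjusted p = 0.77).

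On the mean, 336 probe sets passed, 161 higher and 175 lower in fast cells (124 and 129 genes), 71 and 88 of them by more than 2-fold. Of these, 252 had the same sign in both sets, 20 were called in each set in the same direction, and 235 were called in C6 alone of the 2 sets and 43 in C6SPGFP alone. Of the 336, 148 also passed the test of the difference, so the mean does not describe both sets for them. The count was 216 without C6SPGFP slow replicate 1, 169 without slow replicate 2, 196 without fast replicate 1 and 159 without fast replicate 2. The call for Sfrp4 ended without C6 slow replicate 1 (adjusted p = 0.105), C6 slow replicate 2 (0.0619), C6 fast replicate 2 (0.123), C6SPGFP slow replicate 2 (0.0721), C6SPGFP fast replicate 1 (0.13) or C6SPGFP fast replicate 2 (0.102). It also ended under 6 other settings, the deposited scaling among them, with adjusted p-values from 0.05 to 0.0874. Under the deposited scaling, where the median of all probe sets was 0.5 instead of 0.0026, 14 passed, 100% of them higher against 47.9%.

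On the mean of both sets, 2 of 23 gene lists passed, or 5 with the filter at the 50th percentile, which added astroglial (adjusted p = 0.0129), extracellular matrix (0.0175) and growth inhibitor genes (0.0372), each lower. Oligodendroglial and Schwann genes fell as a list (15 of 18 negative, mean log2 change -0.50, adjusted p = 0.00025; adjusted p = 0.211 with an estimated correlation). Of its members 5 were lower, or 6 adjusted over the list alone, among them Sox10, Cnp and Egr2 (-1.08), a transcription factor of Schwann cell myelination. Proliferation genes rose as a list (28 of 33 positive, median log2 change 0.21, adjusted p = 0.00025; adjusted p = 0.25 with an estimated correlation). Of its members 1 was called, thymidylate synthase (Tyms, 0.63), or 4 adjusted over the list alone. Both calls held in each run that left out an array.

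The other 21 lists did not pass on the mean with the filter chosen beforehand. Astroglial genes had 4 of 19 lower, or 1 higher and 5 lower adjusted over the list alone, with Ndrg2 at -1.55 (list adjusted p = 0.146). Interferon and antigen presentation genes had 4 of 23 higher and 1 lower, the same adjusted over the list alone, with Psmb9 at 0.86 and Irf7, a transcription factor of the interferon response, at -1.33 (0.146). Oxidative stress genes had 5 of 31 higher and 1 lower, or 5 and 2 adjusted over the list alone, with Nqo1 at 1.0 (0.146). Extracellular matrix genes had 1 of 32 higher, fibronectin (Fn1, 0.39), and 4 lower, the same adjusted over the list alone, with Mgp at -1.82 (0.179). Growth factors and receptors had 2 of 65 higher and 8 lower, or 5 and 8 adjusted over the list alone, with Igf2r at 0.68 and the neurotrophin receptor Ngfr at -1.11 (0.303). Adhesion genes had 1 of 34 higher, the proteoglycan Sdc1 (0.51), and 4 lower, or 1 and 5 adjusted over the list alone (0.492). Actin and contractility genes had 4 of 49 lower, also adjusted over the list alone, with the GTPase Rhob at -1.18 (0.303). Ion channels and transporters had 2 of 23 higher and 2 lower, or 3 and 2 adjusted over the list alone (list adjusted p = 0.907). The increases were led by Atp1b1 (2.29 on the probe set used for lists) and Aqp1 (2.51).

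The list adjusted p on the mean was 0.208 for sterol synthesis and for growth inhibitors, 0.216 for oxidative phosphorylation, 0.303 for immediate early genes and 0.35 for regulators of G-protein signalling. It was 0.492 for proteases, neuronal genes, endothelial and mural markers and chemokines, 0.508 for glycolysis, 0.549 for microglial and haematopoietic markers, and 0.791 for heat shock genes and ribosomal proteins. The median and the mean differed in sign for chemokines (-0.026 and 0.017), ion channels (-0.029 and 0.12), heat shock genes (-0.0054 and 0.0082) and ribosomal proteins (-0.0053 and 0.024), with tests pointing up. No list passed with an estimated correlation in any comparison. That form of the test uses only the 4 residual degrees of freedom, so correlation alone does not account for the lost calls. For the oligodendroglial list on the mean the estimated correlation was -0.011, below the preset 0.01. Its unadjusted camera p still rose from 1.32e-05 to 0.00919. The rotation test fry, which asks whether the members of a list move on balance one way without comparing them with other genes, passed 6 lists on the mean, 7 in C6, 0 in C6SPGFP and 8 on the difference.

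**Figure D3:**
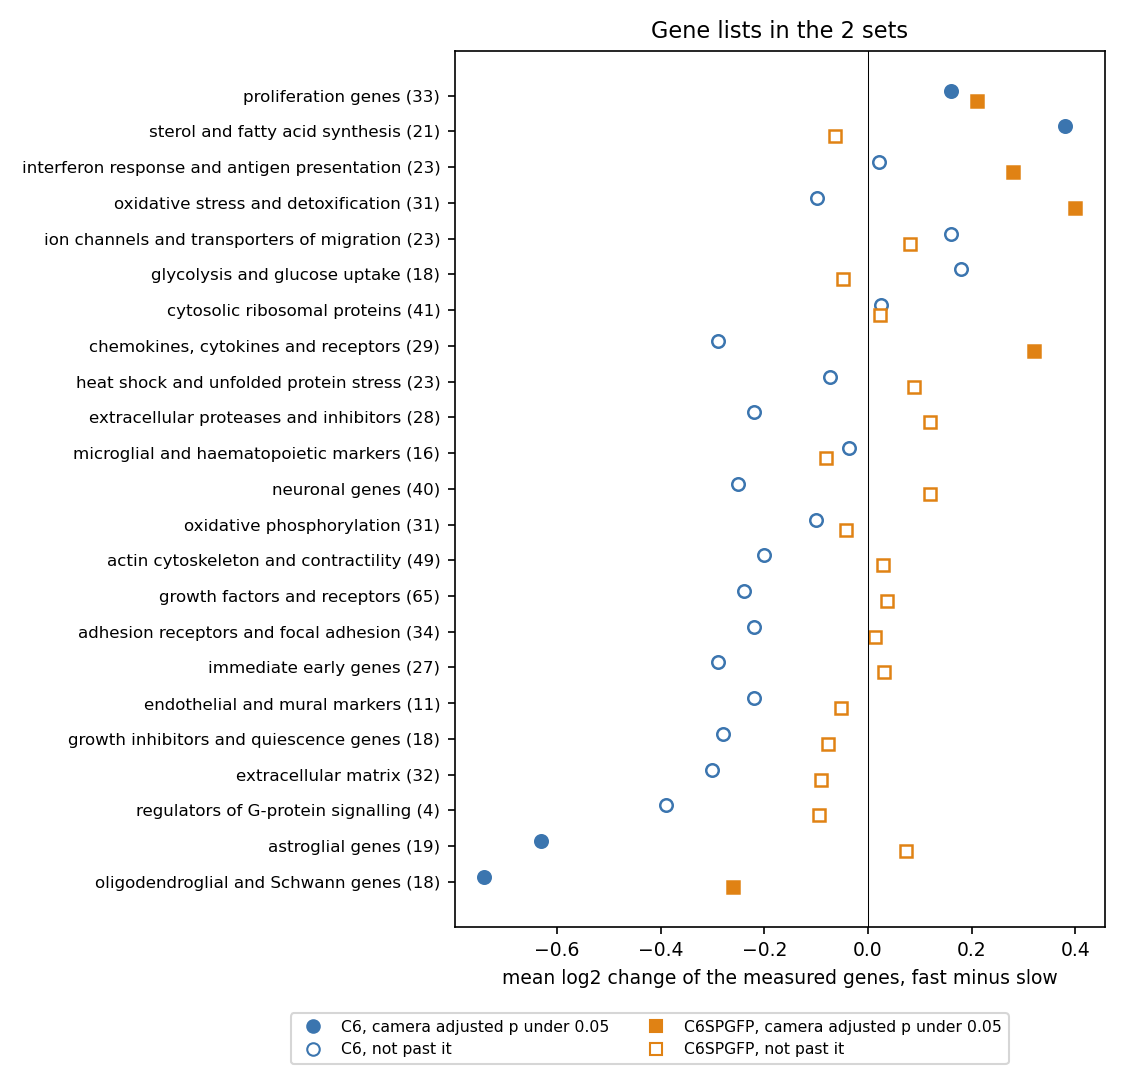
Mean log2 change between fast and slow cells (horizontal axis) of the measured genes of each of 23 lists, with their number in brackets, in C6 (blue circles) and C6SPGFP (orange squares); filled symbols passed camera at 5%. Oligodendroglial and Schwann genes lay at -0.74 and -0.26, and astroglial genes at -0.63 and 0.073.

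The C6SPGFP and C6 sets also differed from each other at both speeds. Mgp was higher in C6SPGFP by 4.32 ± 0.25 (SE) on the log2 scale on the mean of slow and fast cells. Mt3, a metallothionein of the brain, was higher by 3.95 ± 0.14, from 9.44 ± 1.91 to 188 ± 29.6 in slow cells (SD, n = 2), and the myelin proteolipid plasmolipin (Pllp) by 3.92 ± 0.22. S100b was higher by 2.84 ± 0.11 and Sox10 by 3.18 ± 0.16. Fhl2, a LIM domain protein of the cytoskeleton and nucleus, was lower (-4.90 ± 0.13), with 181 ± 23.4 against 6.11 ± 0.548 in slow and 800.0 ± 20.4 against 4.15 ± 0.53 in fast cells. Dab2, an endocytic adaptor, was lower too (-4.38 ± 0.34).

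The other large increases in C6SPGFP were Gas7 (3.97), Aatk (3.91), Calcb (3.63), Reln (3.56), Tubb2b (3.53), the receptor phosphatase Ptprz1 (3.47), the sodium channel Scn7a (3.40) and Cd81 (3.18). The other large decreases were Atp1b1 (-2.96), Dock8 (-2.91), the transcription factors Cebpb (-2.82) and Snai2 (-2.76), Abcb6 (-2.47) and Lama3 (-2.41). They were followed by the cysteine-forming enzyme Cth (-2.35), Mtmr7 (-2.27), the haem oxygenase Hmox1 (-2.26) and muscle enolase (Eno3, -2.22). Adjusted p-values of these 24 genes ran from 2.54e-07 for Tubb2b to 0.000488 for Eno3. Another Dock8 probe set gave 0.415, and smaller differences came from other probe sets of Gas7 (2.56), Ptprz1 (1.41), Scn7a (1.01), Cth (-1.34), Atp1b1 (-1.2) and S100b (0.529). For Aatk, Calcb, Reln, Tubb2b, Ptprz1, Sox10, Cd81, Gas7, Atp1b1, Fhl2 and Lama3 the difference between the sets itself differed between slow and fast cells, with adjusted p-values from 3.64e-06 for Tubb2b to 0.0406 for Gas7. The same held for S100b (adjusted p of the difference 0.000433). Its signal was 408 in C6 against 1226 in C6SPGFP in slow cells, and 65.9 against 1261 in fast cells. Vim was higher by 0.31 ± 0.07 (adjusted p = 0.0134), a direction that turned when each array was scaled to the same median (-0.25) or to the same trimmed mean (-0.06). The call ended without C6 fast replicate 1 (adjusted p = 0.0525), C6SPGFP slow replicate 1 (0.0567) or C6SPGFP fast replicate 2 (0.0555), and without a trend in the moderation (0.11).

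Between the sets 424 probe sets passed in slow cells (220 higher and 204 lower in C6SPGFP), 1042 in fast cells (554 and 488) and 1328 on the mean (686 and 642, with 254 and 168 changed more than 2-fold). Without single arrays the count in slow cells was 197 (C6 slow replicate 1), 154 (C6SPGFP slow replicate 1) and 95 (C6SPGFP slow replicate 2). In fast cells it was 668 (C6 fast replicate 1), 563 (C6SPGFP fast replicate 1) and 509 (C6SPGFP fast replicate 2), and on the mean 862 (C6SPGFP slow replicate 2) and 882 (C6SPGFP fast replicate 2). It was 270 in slow cells when only those arrays were fitted. The share higher was 53.2% in fast cells and 51.7% on the mean, but 38.7% and 38.6% with each array scaled to the same median. In slow cells it was 51.9%. The deposited scaling gave counts of 3 in slow cells, 194 in fast cells and 83 on the mean, with 66.7%, 93.8% and 92.8% higher. The median of all probe sets was then 1.1 in fast cells and 0.57 on the mean, against -0.034 and -0.0094.

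Of the lists, 3 passed between the sets, each relative to the other genes tested. Oligodendroglial and Schwann genes were higher in C6SPGFP (8 of 18 called, also adjusted over the list alone, and none lower; adjusted p = 0.00269; adjusted p = 0.168 with an estimated correlation), with Sox10, S100b and Egr2 (2.70) among them. Adhesion genes were higher (13 of 34 called higher and 2 lower, or 13 and 3 adjusted over the list alone; adjusted p = 0.00269; adjusted p = 0.168 with an estimated correlation), led by Cd81 and Cd9 (1.91), with Sdc1 (-0.91) lower. Ribosomal proteins were lower (35 of 41 negative, median log2 change -0.13, with 5 called, also adjusted over the list alone; adjusted p = 0.038; adjusted p = 0.73 with an estimated correlation). Rpl36 (-0.40) and Rps27l (-0.42) were among them. The call ended without C6 slow replicate 1 (adjusted p = 0.135), C6SPGFP slow replicate 1 (0.104) or C6SPGFP fast replicate 1 (0.0812). Some measures of RNA quality differed with the sets. The Gapdh 3'/5' ratio was 0.984 ± 0.0127 in C6SPGFP and 1.02 ± 0.0227 in C6 (SD, n = 4), and the beta-actin ratio 1.08 ± 0.0298 and 1.02 ± 0.0145. The mean log2 signal of ribosomal proteins was 10.06 ± 0.0748 and 10.20 ± 0.0493. It was taken from the genes of the ribosomal list, so it restates the call of that list and does not explain it. The Gapdh ratio, the beta-actin ratio and the ribosomal mean each had a two-sided exact permutation p of 0.0286, the smallest that the 70 splits allow, and 0.114 after adjustment over 12 tests. For a hybridisation control, the hexokinase ratio and the 5S control the two-sided exact permutation p was 0.0571, 0.114 and 0.171.

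The remaining 20 lists did not pass between the sets. With the filter at the 50th percentile 4 of them did, extracellular matrix (0.0383) and astroglial genes (0.0234), higher in C6SPGFP, and sterol synthesis (0.0339) and oxidative stress (0.0383), lower. The nearest were growth factors and receptors, extracellular matrix, sterol synthesis and oxidative stress, each with an adjusted p of 0.0607, and astroglial genes (0.0616). Of 65 growth factors and receptors 14 were higher and 3 lower in C6SPGFP, or 15 and 4 adjusted over the list alone, with Gfra1 at 2.96 and Ngfr at 2.13. Of 31 oxidative stress genes 3 were higher and 10 lower, or 3 and 12 adjusted over the list alone, with the drug efflux pump Abcb1b at -2.15 and Nqo1 at -1.30. Of 19 astroglial genes 7 were higher and 3 lower, or 9 and 3 adjusted over the list alone, with Mt3 and S100b higher. Lower were the gap junction protein Gja1 (-1.37) and clusterin (Clu, -1.04). The median and mean differed in sign for neuronal genes (-0.012 and 0.21), immediate early genes (-0.10 and 0.10, test pointing down) and ion channels (-0.0049 and 0.053). The test fry passed 11 lists between the sets.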

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

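Of the tests in this part, those of the scale of a single array, of admixed cells, of degraded RNA, of another cell population and of an array or culture batch were chosen only after the result was seen.

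The fast minus slow change differed between the sets for 255 probe sets, found by testing the difference itself, and for 45 of the genes that the fixed rule named for these changes or their difference. The change was higher in C6SPGFP for Ccl2 (6.79), Cyp1b1 (5.96), Rhox5 (5.25), Tubb2b (5.0), Sox10 (4.62), Aatk (4.61), Pdpn (4.58), F3 (4.47), Pmepa1 (4.42), Sncg (4.33), Fst (4.11), Cd81 (3.88), Sv2b (3.67), Bin1 (3.67), Calcb (3.6), Gnrhr (3.55), Jph2 (3.55), Ass1 (3.49), Reln (2.75), Prickle2 (2.71), S100b (2.54), Kifc3 (2.48), Foxs1 (2.38), Plagl1 (1.95), Gper1 (1.69), Spn (1.47) and Cnp (1.31), in log2 units. It was higher in C6 for Prkcb (-1.59), Lama3 (-1.78), Cdc42ep3 (-1.92), Gphn (-2.43), Kcnj10 (-2.69), Basp1 (-2.99), Pde2a (-3.09), Ppp2r2b (-3.10), Lsamp (-3.25), Slc2a5 (-3.38), Olfm1 (-3.49), Cpe (-3.6), Rtn1 (-3.70), Ptgs2 (-3.97), Pou3f3 (-4.23), Il33 (-4.67), Pla2g4a (-5.12) and Atp1b1 (-5.19). By the same test of the difference 4 gene lists stood out, astroglial genes (adjusted p = 0.0059), chemokines (0.0264), sterol synthesis (0.0274) and oxidative stress (0.0264), none of which passed with an estimated correlation. Other genes named in the report had a called difference too, among them Fhl2, Ptprz1, Gas7, Bmp7, Mmp16, Fabp5, Ndrg2, Ackr3, Gstm2 and Acat2.

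The trimmed mean of C6SPGFP fast replicate 1 lay far from those of the other arrays, with a gap of 0.986 of the whole range, above the critical value of Dixon's test for 8 samples. Chance passes that critical value in about 1 of 20 groups, and the other 6 measures per array stayed below it.

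The near absence of correlation between the fast minus slow changes of the sets (r = 0.051) was weighed against noise and against the scale of that array. Corrected for the split-half reliability of each change (0.705 in C6 and 0.541 in C6SPGFP), r was 0.083. That argues against the spread between these replicate arrays as the reason. If the replicates are not separate cultures, noise between cultures is not part of that spread and stays open. Without C6SPGFP fast replicate 1 r was 0.052, which argues against its scale. A difference between the cells of the sets could account for it and was not tested apart from the comparison itself, since the labels do not say how the sets differ.

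In C6 fast cells 8 glial genes were called lower, whereas most genes of the 2 glial lists were not called. The lower level of these 8 could reflect other cells mixed in, degraded RNA or another cell population. Of 2861 tested probe sets with a slow signal of at least 100, 18 lay under 10% of it on both fast arrays, against at most 3 between replicates of a group, which argues against a mixture that leaves at least 10% C6 cells as the whole cause. Of the called glial genes among them 1 of 6 did, Sox10, and the other 5 kept 11.9 to 61.9%. For those 5 such a mixture stays open, but not alone. The share of C6 cells would be the same for every gene, so the remaining C6 cells would also need lower levels of the 18. The highest Gapdh or beta-actin 3'/5' ratio on the C6 fast arrays was 1.052, which argues against degraded RNA, and the hexokinase ratio was 1.98 and 1.57 there against 2.23 and 1.88 on the C6 slow arrays. Of 27 measured markers of microglia, blood cells, endothelium and mural cells, 1 was called higher, Cd37 (14.6 in slow and 53.1 in fast cells). These lists hold only some markers of such cells, and Spn, Lgals3 and Slc2a5, which rose in C6 fast cells, are not on them. Another cell population, on or outside these lists, or a subclone or altered state of C6, stays open.

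The differences between the C6SPGFP and C6 sets were weighed against an array or culture batch that follows the sets. Of the probe sets called between the sets, 188 also had a called difference of the fast minus slow changes. A batch that shifts the slow and fast cells of a set equally would not give this. The pseudocount can make such a shift unequal where the signal is low at a single speed. A batch on the arrays of a single group would give it too. The 188 therefore argue only against an equal shift of a whole set as the whole cause, and not where signals are low. For the other 1140 a batch and a lasting difference between the cells cannot be told apart, since each set would lie in its own batch.

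Other splits of the arrays were counted beside the results. In a fit with 2 groups of 4 arrays, fast against slow called 7 probe sets. Of 35 splits 2 called as many, the real one included, so chance could not be excluded for it by this count. The highest other split called 614 and was the split by set, which points to a structure of the samples that this fit does not take up. For the split by set itself, 1 of 35 splits called as many as the real 614, and the highest other called 7, so chance can be excluded only as far as single arrays can be exchanged. Of the 35 splits, 3 keep the replicates of each group together, with 614, 7 and 0 calls, too few to exclude chance if the replicates are not separate cultures. With the sets kept as terms, the mean of the fast minus slow changes called 336 probe sets and the highest other of the 18 splits within the sets 255 (1 split as high, the real one). The split with 255 swaps fast and slow in 1 set and so equals the test of the difference, and the highest of the remaining splits called 105. The 18 splits are too few for a share under 0.05.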

How the results depend on the processing

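Of the alternatives, scaling to a common trimmed mean was chosen after the data were seen. Counts are given in the order C6, C6SPGFP, their mean, their difference, and C6SPGFP minus C6 in slow cells, in fast cells and on the mean. Under the deposited scaling, with 7018 probe sets tested and C6SPGFP fast replicate 1 left at its own scale, they were 24, 20, 14, 25, 3, 194 and 83, and r between the sets was 0.016. That array then stands far from its replicate, which widens the fitted spread, and 50 of 112 named calls were lost. Fits of only the groups compared, with fewer degrees of freedom, gave 230 against 445 in C6 but 100 against 93 in C6SPGFP. Between the sets they gave 270 against 424 in slow cells and 877 against 1042 in fast cells. For lists on the mean, the filter at the 50th percentile gave 5 (the cause was not tested) and an estimated correlation 0. Vim between the sets turned to -0.253 with arrays scaled to the same median and to -0.064 at the same trimmed mean (the cause was not tested). With each array left out in turn the counts ranged from 279 to 446, 21 to 107, 159 to 303, 123 to 273, 95 to 421, 509 to 1127 and 862 to 1187, r from 0.015 to 0.083, and lists on the mean from 2 to 3. Fewer arrays were then fitted, and the cause was not tested further. With the replicate number as a block the counts were 424, 87, 306, 235, 392, 989 and 1313, with 2 lists, but correlations of replicate deviations between groups of -0.13 to 0.27 did not show that the numbers pair the arrays. The remaining alternatives of scaling, pseudocount, filter and moderation kept these counts within 1.5 times, but ended some list calls, as given with the lists. Detection calls are not used here, so the limit set by signal over background is unknown, and signals of a few units carry little information.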

Other observations

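In this part, the tests on the likeness of the fast cells of the sets and on the sterol list were chosen only after the results were seen, and the genes named below were chosen after their values were seen.

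Of the interferon and antigen presentation genes, the immunoproteasome subunits Psmb9 (log2 change 0.86, adjusted p = 0.00817) and Psmb8 (0.83, 0.0104), the peptide transporter Tap2 (0.89, 0.0325) and the membrane protein Ifitm3 (0.83, 0.0281) were higher in fast cells on the mean of both sets, while Irf7 was lower (-1.33, 0.0175). The list as a whole did not pass on the mean (adjusted p = 0.146). Of 27 immediate early genes 1 rose and 5 fell in C6, or 2 and 5 adjusted over the list alone (list adjusted p = 0.103). There the transcription factor Egr1 rose (0.78, adjusted p = 0.0226) and Ier3 (-1.28, 0.00199), Nr4a1 (-1.70, 0.0104), Egr2 (-1.70, 0.0107) and the phosphatase Dusp6 (-1.24, 0.0239) fell. Of 18 glycolysis genes 2 rose and 1 fell in C6, or 7 and 1 adjusted over the list alone (list adjusted p = 0.32). Pdk1, the kinase that shuts pyruvate dehydrogenase, rose in C6 fast cells by 1.67 (0.00362) and the platelet phosphofructokinase Pfkp by 0.76 (0.0196), whereas the monocarboxylate transporter Slc16a1 fell (-0.66, 0.0415).

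Between the sets, 5 of 18 growth inhibitor and quiescence genes were lower in C6SPGFP on the mean of slow and fast cells and 2 higher, or 6 and 4 adjusted over the list alone, with a list adjusted p of 0.52. Lower were the cell cycle inhibitor Cdkn1a (-1.42, adjusted p = 0.00173), Mdm2 (-1.11, 0.0022), Ccng1 (-1.04, 0.000424), Gadd45a (-1.42, 0.00094) and Gas5 (-1.20, 0.00294), and higher were Gas7 (2.56 on the probe set used for lists, 0.000259) and Pmp22 (0.98, 0.0011). Of 18 glycolysis genes 3 were higher and 6 lower, or 4 and 7 adjusted over the list alone (list adjusted p = 0.552). The glucose transporter Slc2a1 (-1.83, 0.000125) and Hk1 (-0.69, 0.0244) were lower, and Ldhb (1.03, 0.000798) and Pfkm (0.63, 0.0272) higher. Of 40 neuronal genes 6 were higher and 2 lower, also adjusted over the list alone (list adjusted p = 0.52). Gad1 (2.73, 1.63e-05) and secretogranin (Scg2, 3.03, 0.000215) were higher, and Penk (-1.61, 4.42e-05) and Calb1 (-0.81, 0.0286) lower. Of 32 matrix genes 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone (list adjusted p = 0.0607). Brevican (Bcan, 1.99, 0.000385) and biglycan (Bgn, 1.25, 0.0027) were higher and P4ha1 lower (-0.56, 0.0444).

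Fast cells of both sets could have approached a shared state. Across probe sets, r between the sets was 0.907 to 0.913 for fast arrays and 0.936 to 0.953 for slow arrays. The highest fast value minus the lowest slow value was -0.024, so each fast pair was less alike than each slow pair, which argues against convergence of the transcriptome as a whole. The probe sets called in both sets are a separate result.

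The call of the sterol list in C6 could reflect a difference between replicate arrays. The list mean differed by 0.743 between the C6 slow replicates (8.16 and 8.91, log2) and by 0.381 between fast and slow C6 cells, or -0.06 in C6SPGFP, and the ratio of the largest fast minus slow to the largest replicate difference was 0.51, as this explanation predicts. Sqle, squalene epoxidase, had a signal of 650.2 in C6 slow replicate 1 and 1219 in replicate 2, against 1352 and 1558 in fast cells. Whether the replicates differed in culture conditions is not given in the sources used here.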
